A study of Mus musculus with 9 samples.

How the data were processed

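Poly-A RNA was sequenced from endothelial cells sorted from the lungs of 9 individual mice on the B6 background. 4 mice were wild type (WT 1, 4, 5 and 6) and 5 were littermates carrying the V154M substitution in STING (VM 3, 7, 8, 9 and 10), with the numbers taken from the labels. Per the labels' protocols, each lung was enzymatically dissociated and live cells negative for CD45, EPCAM and PDGFRa and positive for CD31 were sorted into lysis buffer. These gates are meant to remove leukocytes, epithelial cells and most fibroblasts and to keep endothelium. The small amount of RNA was turned into full-length cDNA by oligo-dT priming and template switching, amplified by PCR and sequenced as paired-end reads on a nanoball sequencer. No molecular identifiers are named in the protocol, so amplified copies count as separate reads.

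The data are 1 table for the whole series with 15056 gene symbols, 9 columns of values per gene, and the authors' own comparison. All 9 columns matched a mouse by its label, and 0 columns of values were left unmatched. Per the submitters' processing notes, the genome build was mm10 and the tools were FastQC, Trimmomatic, cutadapt, Bowtie2, Bowtie, STAR, RSEM, kallisto, HISAT2, TopHat2, featureCounts, Picard and DESeq2. The notes give neither a role nor a version for any of them, so the aligner, the counter, the annotation, the handling of strand and of reads shared between similar genes, and any filter are not given in the sources used here. The values are a never-negative signal, normalized read counts as DESeq2 writes them, which the authors deposited in place of raw counts. In each column the values were whole multiples of 1 number, so dividing by it recovered whole reads for 100% of values within 1e-06. The authors also deposited a log2 fold change, the same change as a linear ratio, a p-value and an adjusted p-value, and a column of −log10 adjusted p-values for VM against WT. 1167 adjusted p cells of that deposited table equal 1 and have no −log10 value. 241 genes were at 0 in every library and 0 symbols occurred more than once.

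The recovered totals were 21915920 to 23248022 reads in WT and 22593440 to 23674992 in VM. With 3 reads taken as the floor for a gene at 0, the limit was 2.68 to 3.20 normalized reads per library. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Gene coordinates are for GRCm38 (mm10), counted from 1, taken from GENCODE M21 by symbol, and 14359 of the 15056 symbols matched exactly 1 gene. Genes of closely similar sequence are reported as uncertain, because it is not given how reads shared between them were counted. They include the H2-Q, Gbp, Tgtp, Oas1, Apol9 and Serpina3 families and the globins.

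Because the table holds normalized values, the main test was limma 3.58.1 (R 4.3.3; empirical Bayes with trend and robust settings) on log2(value + 1) for the 13997 genes with a value of at least 1 in at least 4 mice. All 9 mice entered the fit without covariates, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Log2 fold changes are on the log2(value + 1) scale, VM minus WT, with standard errors, and understate the change of genes with few reads. A rise of a gene written as a fold is instead the ratio of the mean normalized reads of VM and WT. Bounds for genes at 0 in a group use the floor, and counts of genes changed at least 2-fold use the fitted values. Levels are normalized reads as mean ± SD. Gene lists were tested with limma's camera (preset correlation 0.01, 2-sided, at least 3 tested members, Benjamini-Hochberg over the lists), again with an estimated correlation between genes, and with fry. Within each list a second count was adjusted over the list alone. A list score is the mean log2 value of its tested members in a library. Scores and principal components (of the 1000 most variable genes) were compared by 2-sided exact permutation tests, for which the 126 splits of 9 mice into 4 and 5 give a smallest p of 0.00794. The mice are separate animals, and p-values of genes and scores set a difference against the spread between them. Camera p-values instead compare the members of a list with the other tested genes. With the preset correlation they are too small where members vary together. The estimated correlation was 0.27 for type I interferon-stimulated genes and 0.84 for erythroid markers. Unless an estimated correlation is named, camera p-values use the preset one, also under the alternatives. Neither sex, litter, age nor batch of a mouse is given in the labels used here.

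The groups, the main test, the rule for naming genes, the gene lists and most alternatives were fixed before the data were examined. The rule named the mutated gene; the 10 largest rises and 10 largest falls among genes past the threshold, with no overlap between the groups and a mean above the median of the tested genes; up to 4 members with the smallest p past the threshold of each pathway or endothelial list, or otherwise its most abundant member; and the 2 most abundant members and the member with the smallest p of each list of other cell types or sample quality. Unnamed gene models, pseudogenes, receptor segments and sex-linked genes were left out of the largest changes. Other genes are named in places and are said there to have been chosen after their values were seen. The values of 2 genes past the threshold are not reported here. The lists covered type I interferon-stimulated genes, interferon gamma-inducible GTPases, other interferon gamma-responsive genes, MHC class I and class II presentation, chemokines, adhesion molecules, high endothelial venule genes, NF-kB targets, STING signalling, interferon ligands and receptors, the unfolded protein response, cell death, cell cycle, angiogenesis, coagulation, vascular tone and barrier, mesenchymal transition with TGF-beta, and complement. They also covered markers of general capillary, aerocyte, arterial, venous, lymphatic and all endothelium. Markers of T and NK cells, B cells, myeloid cells, neutrophils, all leukocytes, platelets, erythroid cells, epithelium, fibroblasts, smooth muscle and mesothelium, genes induced by dissociation, mitochondrially encoded genes and sex-linked genes completed the set. The mesothelial list had 2 tested members and the mitochondrial list 0, and neither was tested.

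The alternatives were quantile normalization, median centring, limma without trend, array weights, no filter and a minimum of 5, pseudocounts of 0.1 and 5, covariates for Xist, for the pan-leukocyte score and for the dissociation score, and leaving out each mouse. Stricter thresholds were an adjusted p under 0.01 or at least a 2-fold change. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood test, with and without Xist as a covariate) and DESeq2 1.42.0 on the recovered reads, the erythroid score as a covariate, and leaving out WT 1 and VM 10 together. The edgeR test on the recovered reads called 89 genes higher and 15 lower in VM. The limma procedure was tested on simulated data, 10 sets of the 9 libraries with 200 changed genes each and 14108 genes tested on average. It recovered 7.61% of genes changed 1.5-fold, 53.9% of those changed 2-fold and 90.8% of those changed 4-fold, with the right sign for 100% of them. Of its calls 7.84% were false, more than the adjusted p threshold of 0.05 stands for. A changed list was found in 10 of 10 sets and an unchanged list in 0. Genes were simulated independently of each other, so these sets do not check list p-values where members are correlated. They also held no sex-linked imbalance and no library set apart as VM 10 was.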

Results

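Mice with a gain-of-function STING develop lung inflammation, and the series concerns the part that radioresistant cells play in it. STING is an endoplasmic reticulum adaptor that relays the sensing of cytosolic DNA to interferon and NF-kB responses. V154M is the mouse counterpart of a human variant that causes STING-associated vasculopathy with onset in infancy. RNA was measured in CD31-positive endothelial cells sorted from the lungs of 4 wild type (WT) and 5 STING V154M (VM) littermates. The comparison asks which transcripts differ between the genotypes in these cells. The libraries held 21915920 to 23674992 recovered reads. The mutated gene, under its older symbol Tmem173 (chromosome 18, 35733679 to 35740554, minus strand), did not pass the test between the groups. It had 378 ± 117 normalized reads in WT (SD, n = 4) and 348 ± 40.1 in VM (SD, n = 5), with a log2 fold change of -0.06 ± 0.23 (SE, limma adjusted p = 0.952). Its values were 403, 211, 482 and 415 in WT 1, 4, 5 and 6 and 354, 376, 361, 369.5 and 278 in VM 3, 7, 8, 9 and 10. A point mutation need not alter the transcript level, so this value does not check the labels.

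CD31-positive lung samples of VM mice held more RNA of antigen presentation and interferon-response genes than those of WT littermates. Cd74, the invariant chain that chaperones MHC class II molecules (chromosome 18, 60803848 to 60812652), rose 6.64-fold, from 28359 ± 12438 to 188218 ± 14998 normalized reads (SD, n = 4 and 5). Its log2 fold change was 2.84 ± 0.26 (SE, limma adjusted p = 0.000374). Serpina3g, an intracellular inhibitor of cysteine and serine proteases (chromosome 12, 104236245 to 104241939), rose 9.02-fold with the smallest p of all 13997 tested genes (3.17 ± 0.23, limma adjusted p = 5.6e-05). The antiviral gene Rsad2 rose 5.01-fold (2.41 ± 0.35, limma adjusted p = 0.00940). Among the fewer genes that fell was Reln, a secreted glycoprotein made by lymphatic endothelium (chromosome 5, 21884454 to 22344702), from 1164 ± 434 to 407 ± 106 normalized reads (-1.48 ± 0.27, limma adjusted p = 0.0207). Transcripts of myeloid cells were also higher in the VM samples, whereas no pan-endothelial marker passed the test.

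Across the 13997 tested genes, 122 were higher and 19 lower in VM at a Benjamini-Hochberg adjusted p under 0.05 (limma), of which 108 and 14 changed at least 2-fold. At an unadjusted p under 0.05 the counts were 803 and 619. In 632 of all tested genes every VM mouse lay apart from every WT mouse, against 222 (1.59%) by chance. The 10 largest rises named by the rule were Apol11b, Serpina3f, Serpina3g, Cd74, Tgtp1, Rsad2, H2-DMa, Apol9b, Ciita and H2-Eb1, with log2 fold changes from 2.17 to 4.55. Apol11b, of the apolipoprotein L family (chromosome 15, 77633946 to 77643286), had the largest rise among the genes that the rule admits, which are above the median in abundance and do not overlap between the groups. It rose from 199 ± 169 to 4315 ± 2733 normalized reads (4.55 ± 0.71, limma adjusted p = 0.0245). With the erythroid score as a covariate Apol11b had a log2 fold change of 1.97 ± 0.27 (limma adjusted p = 0.0241). Its call ended when WT 4, WT 5, VM 3, VM 8 or VM 10 was left out (limma adjusted p 0.0125 to 0.0762 with 1 mouse left out). Serpina3f reached 4700.5 ± 2299 normalized reads against 459 ± 269.5 in WT (3.39 ± 0.47, limma adjusted p = 0.0122). Of the 46 named genes past the threshold, 28 kept their call with each mouse left out in turn. The count of higher genes fell to 53 without WT 4 and to 68 without VM 3, and without VM 10, whose library differed from the rest as described below, 96 genes were higher and 14 lower. The count of lower genes was 31 without WT 1, 7 to 9 without WT 4, 5 or 6 or VM 9, and 11 without VM 3 or VM 8. Of 37 gene lists, 18 passed with camera's preset correlation and 6 with an estimated correlation, and all 6 were higher in VM.

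All 11 tested members of the MHC class II presentation list had higher means in VM, and 8 of them rose (9 adjusted over the list alone). This list had the smallest p of all lists when the correlation between genes was estimated (limma camera adjusted p = 8.1e-22 with the preset and adjusted p = 0.00845 with an estimated correlation). Its median log2 fold change was 1.99. With Xist as a covariate 8 of the 11 were called and with the pan-leukocyte score 2. The median was 1.70 and 2.46, and the list passed with both. Besides Cd74, the class II chains H2-Aa (5155 ± 2069.6 to 19337 ± 2144 normalized reads, 1.99 ± 0.23, limma adjusted p = 0.00129) and H2-Eb1 (2.17 ± 0.27, limma adjusted p = 0.00247) rose. So did the peptide-loading genes H2-DMa (2.41 ± 0.29, limma adjusted p = 0.00247) and H2-DMb1 (1.92 ± 0.22, limma adjusted p = 0.00129). These structural genes lie on chromosome 17. Ciita, the transcriptional activator of class II genes (chromosome 16, 10480059 to 10528418), rose from 316 ± 64.7 to 1641 ± 892 normalized reads (2.22 ± 0.36, limma adjusted p = 0.0139). This call ended without WT 4 or WT 5 (limma adjusted p 0.0105 to 0.0573 with 1 mouse left out). The list score was 9.44 ± 0.25 in WT and 11.24 ± 0.08 in VM (SD), an exact p of 0.00794, the smallest that 4 against 5 mice can give. In the same libraries the pan-leukocyte score was 1.45 and the erythroid score 2.07 log2 units higher in VM (exact p = 0.0159 and 0.00794).

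Of 22 tested genes of MHC class I presentation, 9 rose (19 adjusted over the list alone) and all 22 had higher means (limma camera adjusted p = 1.6e-22, and adjusted p = 0.0508 with an estimated correlation). Tap1, a subunit of the peptide transporter, rose 3.32-fold (1.80 ± 0.29, limma adjusted p = 0.0139), although not without WT 4 or VM 10 (limma adjusted p 0.00533 to 0.0549 with 1 mouse left out). Nlrc5, the activator of class I genes, rose 3.06-fold (1.56 ± 0.21, limma adjusted p = 0.00345). The classical class I chain H2-K1 rose from 44273 ± 9219 to 90429 ± 10419.7 normalized reads (1.05 ± 0.17, limma adjusted p = 0.00948). H2-Q7 was called 2.73-fold higher (limma adjusted p = 0.00467), but the H2-Q genes are near-identical and how their reads were divided is not given in the sources used here. Of the 22 genes 3 were called with Xist as a covariate, 0 with the pan-leukocyte score and 5 without VM 10. The median was 0.56, 1.04 and 0.67, against 0.64 in the main fit, and the list passed in all of these (camera adjusted p = 4.6e-09, 2.5e-13 and 1.7e-21).

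**Figure D1:**
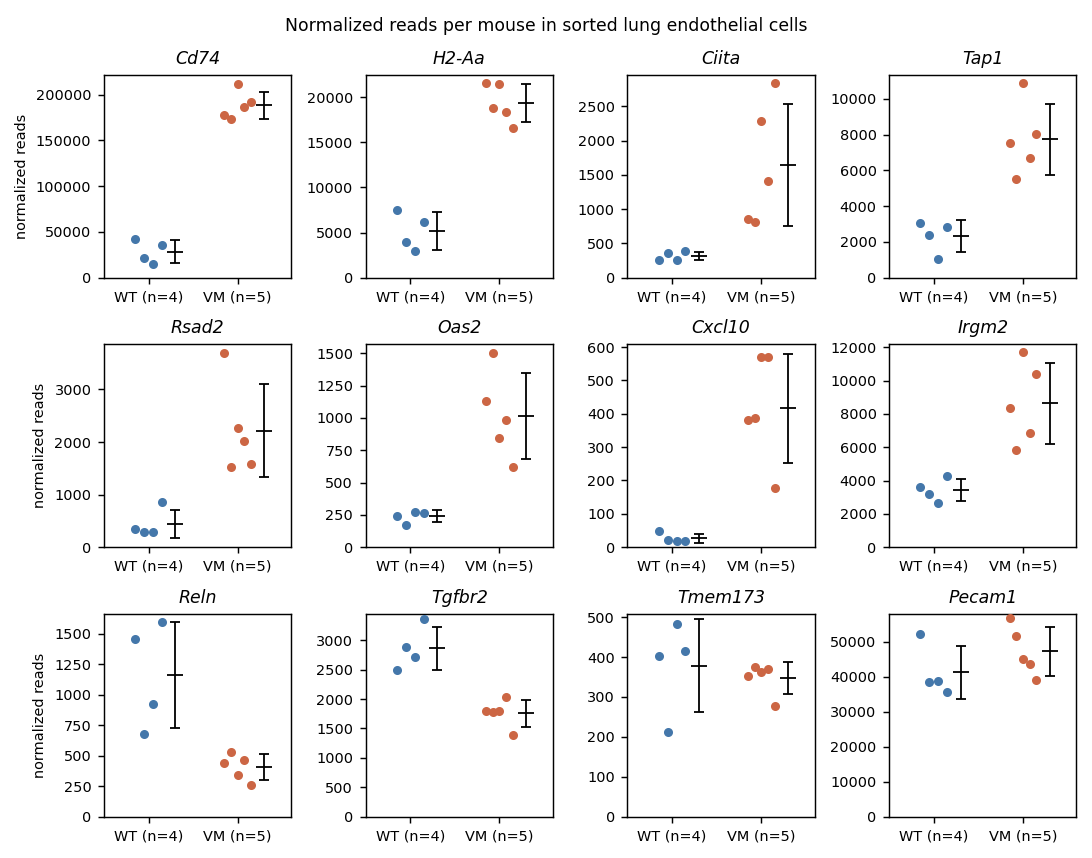
Normalized reads (vertical axes, from 0) of 12 genes in each WT mouse (blue, n = 4) and VM mouse (red, n = 5), with the mean and SD beside the points. In VM, Cd74 averaged 188218 against 28359 normalized reads in WT, while Tmem173 and Pecam1 overlap between the groups.

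Type I interferon-stimulated genes were the largest list, with 53 tested members. Of these, 18 rose (42 adjusted over the list alone) and 51 had positive fold changes. Their median was 0.86 (limma camera adjusted p = 7.4e-43, and adjusted p = 0.0206 with an estimated correlation). Cxcl10, a chemokine for activated T cells (chromosome 5, 92346638 to 92348889), rose 15.7-fold from 26.5 ± 14.4 to 417 ± 164 normalized reads (3.93 ± 0.40, limma adjusted p = 0.000858). Zbp1, a nucleic acid sensor that can trigger necroptosis, rose 5.88-fold (2.57 ± 0.28, limma adjusted p = 0.00114). The oligoadenylate synthetases Oas2 and Oas1a, which activate RNase L against viral RNA, rose 4.25-fold and 3.11-fold (2.04 ± 0.24 and 1.68 ± 0.22, limma adjusted p = 0.00129 and 0.00272), with the caution that Oas1a has close copies. With Xist or the pan-leukocyte score as a covariate 10 and 7 of the 53 were called, and the median was 0.57 and 1.42, with the list passing in both. The score of this list was 9.09 ± 0.22 in WT and 10.18 ± 0.20 in VM (SD, exact p = 0.00794), in libraries whose pan-leukocyte score was 1.45 log2 units higher.

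Of 22 tested interferon gamma-inducible GTPases, which act against intracellular microbes, 9 rose (18 adjusted over the list alone, limma camera adjusted p = 2.8e-23, and adjusted p = 0.0508 with an estimated correlation). They included Tgtp1 (5.58-fold, 2.46 ± 0.40, limma adjusted p = 0.0207), Irgm2 (2.52-fold, 1.31 ± 0.21, limma adjusted p = 0.00940), Irgm1 (2.23-fold, limma adjusted p = 0.0139) and Gbp7 (2.20-fold, limma adjusted p = 0.0223). Without WT 4 the calls of Tgtp1, Irgm1 and Gbp7 ended (limma adjusted p = 0.0717, 0.0627 and 0.0760). The call of Tgtp1 also ended without VM 3 or VM 10 and that of Gbp7 without WT 5 or VM 3. Of 22 other interferon gamma-responsive genes, 9 rose (14 adjusted over the list alone, limma camera adjusted p = 1.3e-18, and adjusted p = 0.00867 with an estimated correlation). Apol9b and Apol9a, near-identical neighbours in sequence, rose 4.71-fold and 6.29-fold (2.29 ± 0.25 and 2.56 ± 0.32, limma adjusted p = 0.00114 and 0.00243). Ubd, a ubiquitin-like protein, had 3 reads in all WT libraries together and 93.1 ± 70.8 normalized reads in VM. This is a ratio of 130 with a 95% counting interval of 44.3 to 634 (limma adjusted p = 0.00247). Of the GTPases 3 were called with Xist as a covariate, 0 with the pan-leukocyte score and 5 without VM 10, and of the other interferon gamma-responsive genes 8, 4 and 8. In the same order the median of the GTPases was 1.15, 1.499 and 1.23, against 1.26 in the main fit. That of the other interferon gamma-responsive genes was 0.91, 1.54 and 1.23, against 1.15, and both lists passed in all of these.

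Among 17 leukocyte-attracting chemokines, 3 rose (5 adjusted over the list alone). Their median was 1.21 (limma camera adjusted p = 1.2e-06, and adjusted p = 0.00867 with an estimated correlation). With the pan-leukocyte score as a covariate 1 of the 17 was called, the Cxcl10 described above. The median then fell to 0.35, while the list still passed (camera adjusted p = 0.0183). The Xist covariate left 3 called (median 0.83, camera adjusted p = 5.6e-05). Ccl5 rose from 6.52 ± 4.63 to 82.7 ± 19.3 normalized reads (3.74 ± 0.58, limma adjusted p = 0.00725). Cxcl9 rose from 5.73 ± 7.05 to 169 ± 142 (5.19 ± 0.92, limma adjusted p = 0.0175), though not without WT 4 (limma adjusted p 0.0102 to 0.0642 with 1 mouse left out). Of 24 cell death genes, 2 rose (4 adjusted over the list alone, limma camera adjusted p = 0.00116, and adjusted p = 0.0365 with an estimated correlation). They were Zbp1 and the inflammasome protease Casp1 (3.92-fold, 2.05 ± 0.30, limma adjusted p = 0.00556). Both are also interferon-responsive. The list lost its call with the pan-leukocyte score as a covariate, with 1 gene called (median 0.24 against 0.16, camera adjusted p = 0.105), and kept it with Xist (median 0.16, camera adjusted p = 0.0254). Of 18 complement genes, 1 rose (7 higher and 2 lower adjusted over the list alone, limma camera adjusted p = 1.0e-05, and adjusted p = 0.0508 with an estimated correlation). It was C4b, at 0 reads in WT and 46.9 ± 29.3 normalized reads in VM, at least 15.7-fold higher against a floor of 3 reads per library (limma adjusted p = 0.00247). With C4b at this bound the median of the list stayed 0.79. No complement gene was called with the pan-leukocyte score as a covariate (median 0.85, camera adjusted p = 0.0128), and 3 were higher and 2 lower with Xist (median 0.94, camera adjusted p = 0.00540). Scores of chemokine, cell death and complement genes each separated the groups with an exact p of 0.00794. Transcripts of leukocytes, which make several of these chemokines and complement factors, were higher in the same VM libraries.

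Of 21 tested genes of cytosolic DNA sensing and the STING pathway, 1 rose (also adjusted over the list alone), the interferon regulator Irf7 (2.63-fold, 1.41 ± 0.20, limma adjusted p = 0.00486). The list passed only with the preset correlation (limma camera adjusted p = 0.0300, and adjusted p = 0.343 with an estimated correlation). That call was lost without WT 1, WT 4, WT 6 or VM 7 (camera adjusted p 0.00243 to 0.145 with 1 mouse left out). It was also lost with the Xist or pan-leukocyte covariate and without trend (camera adjusted p = 0.363, 0.0504 and 0.0543). Of 10 tested interferon receptors, kinases and signal transducers, 2 rose (2 adjusted over the list alone, limma camera adjusted p = 0.0105, and adjusted p = 0.0677 with an estimated correlation). They included the transducer Stat2 (1.68-fold, 0.75 ± 0.15, limma adjusted p = 0.0262). Its call ended without WT 4 or 6 or VM 3, 8, 9 or 10 (limma adjusted p 0.0268 to 0.0789 with 1 mouse left out). With Xist as a covariate the list lost its call, with 1 member called (camera adjusted p = 0.131). It passed with 0 members called with the pan-leukocyte score and 0 without VM 10 (camera adjusted p = 0.0395 and 0.00305). No ligand of this list was tested. Ifnb1 and Ifna2 are not among the symbols of the table, and Ifng and Ifna4 had reads in too few libraries. Ifng had 5 reads in WT 5, 1 in VM 8 and 0 in the others, and Ifna4 had 0 in all 9.

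No single member of the NF-kB target, adhesion, high endothelial venule, unfolded protein response or cell cycle lists passed the threshold in limma, and none did when adjusted over the list alone. The 24 NF-kB targets had a median of 0.23 and passed as a list with the preset correlation only (limma camera adjusted p = 0.0119, and adjusted p = 0.508 with an estimated correlation). They did not pass without WT 1 or VM 7 (camera adjusted p 0.000482 to 0.202 with 1 mouse left out). Nor did they with array weights or with the pan-leukocyte or erythroid covariate (camera adjusted p = 0.116, 0.520 and 0.869). They passed with Xist as a covariate, with 1 member higher (camera adjusted p = 0.00103). Their most abundant member, the feedback inhibitor Nfkbia, had 20776 ± 3884 and 22861 ± 6496 normalized reads in WT and VM. The 17 adhesion molecules did not pass in the main fit (limma camera adjusted p = 0.0946). They passed without VM 10 (camera adjusted p 0.0165 to 0.252 with 1 mouse left out), without WT 1 and VM 10 together (0.0211) and with the erythroid covariate (0.0131). Pecam1, the CD31 antigen used for sorting, had 41262 ± 7491 normalized reads in WT and 47251 ± 7089 in VM (0.20 ± 0.16, limma adjusted p = 0.752). The 10 high endothelial venule genes did not pass either (limma camera adjusted p = 0.651). Their mean fold change and test were positive (0.29) and their median negative (-0.04), with Il6st at -0.00. Neither the 22 unfolded protein response genes (limma camera adjusted p = 0.227, with Hspa5 at 0.07 ± 0.25) nor the 32 cell cycle genes (0.917, with Pcna at 0.01 ± 0.15) passed. The former did without WT 1 or VM 9 (camera adjusted p 0.0128 to 0.935 with 1 mouse left out). They also passed without WT 1 and VM 10 together (0.0155) and with the dissociation (0.0171) or erythroid covariate (0.000827). For cell cycle genes the mean and median were negative (-0.04 and -0.16) and the test direction positive.

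**Figure D2:**
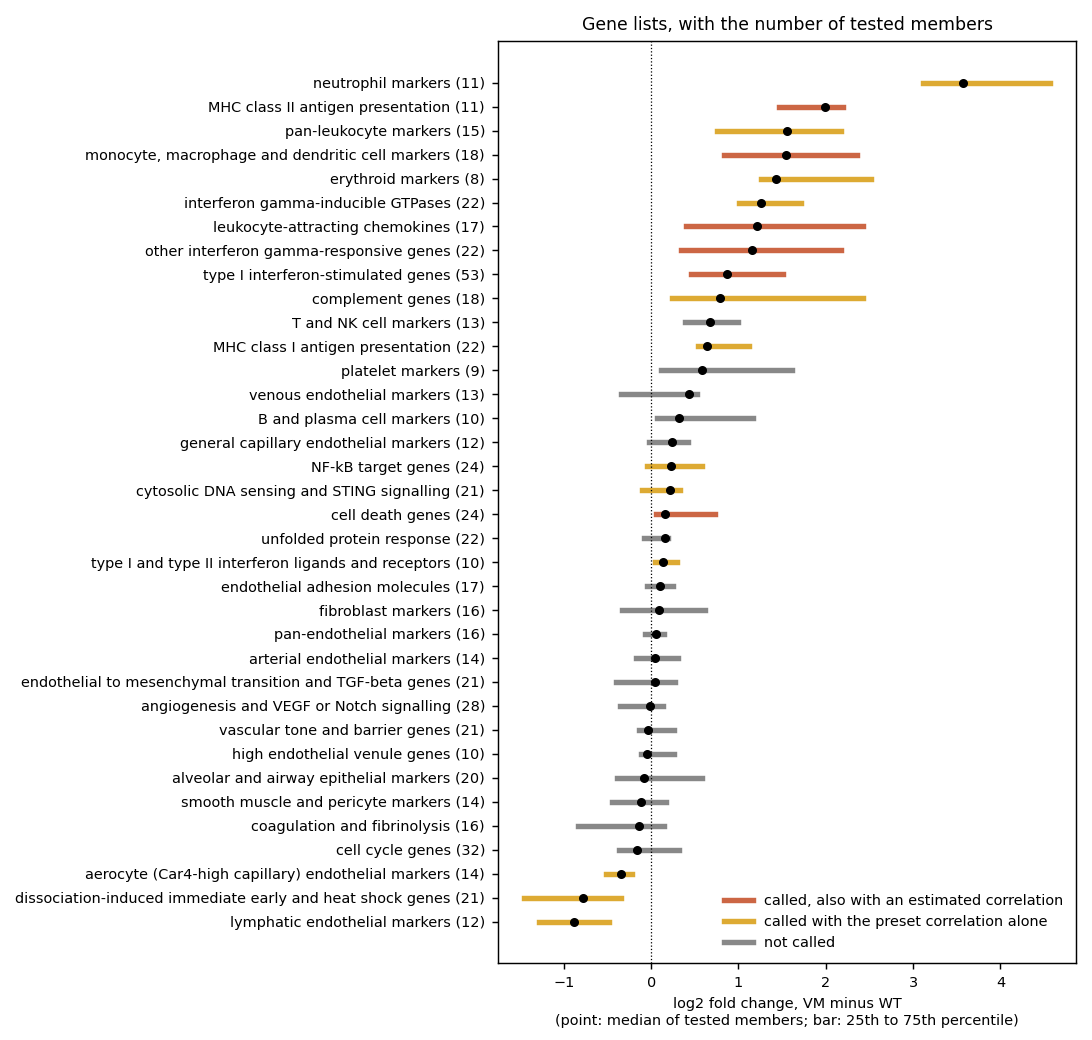
Median (point) and 25th to 75th percentile (bar) of the log2 fold changes, VM minus WT, of the tested members of 36 gene lists, sorted by median; the sex-linked list is left out. Red bars mark the 6 lists that passed also with an estimated correlation, yellow those that passed with the preset correlation alone and grey those that did not pass.

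The 10 largest falls named by the rule were Reln, Lama4, Flrt3, Dhrs3, Lmcd1, Rftn2, Ltbp4, Tgfbr2, Ypel2 and Ipo11, with log2 fold changes from -1.48 to -0.59. Lama4, a laminin chain of vascular basement membranes, fell from 641 ± 59.4 to 275 ± 54.6 normalized reads (-1.24 ± 0.19, limma adjusted p = 0.00630). Dhrs3, a retinaldehyde reductase, fell from 25085 ± 3077 to 11355 ± 3303 (-1.19 ± 0.21, limma adjusted p = 0.0150). Lmcd1, a transcriptional cofactor, fell from 1090.2 ± 441 to 455 ± 55.9 (-1.19 ± 0.22, limma adjusted p = 0.0203). The type II receptor of TGF-beta, Tgfbr2 (chromosome 9, 116084293 to 116175360), fell from 2860.1 ± 367 to 1757 ± 232 (-0.70 ± 0.14, limma adjusted p = 0.0297). Ltbp4, which binds latent TGF-beta, fell from 1274 ± 97.2 to 785 ± 151 (-0.71 ± 0.15, limma adjusted p = 0.0415). Only Lama4 and Lmcd1 kept their calls with each mouse left out in turn. Rftn2, Ypel2 and Ipo11 lost theirs whichever mouse was left out (limma adjusted p up to 0.106, 0.151 and 0.112). Dhrs3 lost it without WT 4 (limma adjusted p 0.0116 to 0.0624 with 1 mouse left out) and Reln without WT 1, WT 6 or VM 8 (0.0156 to 0.0611). Tgfbr2 lost its call without WT 4, 5 or 6 or VM 3, 7 or 8 (limma adjusted p 0.0293 to 0.0966 with 1 mouse left out). Flrt3 lost it without WT 4, 5 or 6 or VM 3, 8, 9 or 10 (0.0143 to 0.134) and Ltbp4 in all cases but without VM 3 (0.0226 to 0.125).

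Lymphatic endothelial markers were lower in VM, with 11 of 12 tested members below WT. 1 of them was past the threshold over all genes (Reln) and 6 adjusted over the list alone. The list passed with the preset correlation (median -0.89, limma camera adjusted p = 2.1e-06) and in fry (adjusted p = 0.0357), but not with an estimated correlation (adjusted p = 0.111). With the pan-leukocyte score as a covariate it did not pass (median -0.43, camera adjusted p = 0.338), and with Xist it passed with 5 members lower (median -1.30, camera adjusted p = 2.0e-07). Its score was 9.79 ± 0.25 in WT and 8.97 ± 0.56 in VM (SD, exact p = 0.0317). Aerocyte markers, of the gas-exchange capillaries, were also lower (median -0.35, limma camera adjusted p = 0.00117, and adjusted p = 0.508 with an estimated correlation). None of the 14 members was called, and the list was not called without VM 7 (camera adjusted p 6.0e-06 to 0.0931 with 1 mouse left out) or with the pan-leukocyte score as a covariate (median -0.25, camera adjusted p = 0.675). It was called with Xist as a covariate, with 1 member lower (median -0.45, camera adjusted p = 0.00432). Their most abundant member Cyp4b1 had 211454 ± 20398 normalized reads in WT and 160269 ± 16310.3 in VM (-0.40 ± 0.15, limma adjusted p = 0.361). General capillary markers did not pass in the main fit (median 0.24, limma camera adjusted p = 0.125). They passed without WT 1, VM 8 or VM 10 (camera adjusted p 0.0101 to 0.556 with 1 mouse left out), without WT 1 and VM 10 together (0.00872) and with the dissociation (0.0483) or erythroid covariate (0.00116). Among them Gpihbp1 was at 0.63 ± 0.25 (limma adjusted p = 0.413, and 0.0252 without WT 1). Arterial markers (limma camera adjusted p = 0.732, Efnb2 0.15 ± 0.15) and venous markers (0.205, Prss23 -0.44 ± 0.29) did not pass, although the venous list did with the erythroid covariate (0.0472). It had 2 members higher and 1 lower adjusted over the list alone. Arterial and venous means were negative (-0.11 and -0.06), their medians (0.04 and 0.43) and tests positive. No general capillary, arterial or pan-endothelial marker passed adjusted over the list alone. The 16 pan-endothelial markers had nearly equal scores ( 12.97 ± 0.11 in WT and 12.99 ± 0.10 in VM, exact p = 0.786). As a list they did not pass (limma camera adjusted p = 0.699, Cldn5 0.10 ± 0.17).

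Vascular function lists were not called in the main fit. The 28 angiogenesis genes had a limma camera adjusted p of 0.137, with 0 members past the threshold and 2 lower adjusted over the list alone. Their most abundant member Nrp1, a co-receptor of VEGF, was at -0.52 ± 0.17 (limma adjusted p = 0.264). The list passed without WT 6 (camera adjusted p 0.0348 to 0.432 with 1 mouse left out). Coagulation genes (limma camera adjusted p = 0.321, Thbd -0.17 ± 0.26) and genes of vascular tone and barrier (0.782, mean 0.01, median -0.03, test positive) did not pass, with 0 members called over the list alone. Coagulation genes passed as lower with Xist as a covariate (camera adjusted p = 0.0237, and 0.0117 in edgeR). Of 21 genes of mesenchymal transition and TGF-beta, 1 fell, also adjusted over the list alone, Tgfbr2 (limma camera adjusted p = 0.699, mean 0.02, median 0.04, test negative). This list passed as lower with the pan-leukocyte or erythroid covariate (camera adjusted p = 0.0271 and 0.00630).

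Transcripts of other cell types were present after the sort and some differed between the groups. Of 18 monocyte, macrophage and dendritic cell markers 4 rose (11 higher and 1 lower adjusted over the list alone). The list passed (limma camera adjusted p = 3.3e-11, and adjusted p = 0.00845 with an estimated correlation), also with the pan-leukocyte score as a covariate but with 0 members called (median 1.12 against 1.54, camera adjusted p = 0.00896). The Xist covariate gave 4 higher and 1 lower (median 1.90, camera adjusted p = 1.7e-08). Tyrobp, a signalling adaptor of myeloid receptors, rose from 55.4 ± 18.9 to 304 ± 145 normalized reads (2.39 ± 0.35, limma adjusted p = 0.00564). The others, outside the rule for named genes and picked once their values were seen, were Csf1r (3.36 ± 0.63), Itgam (3.84 ± 0.79) and Fcer1g (1.72 ± 0.25). The macrophage lysozyme Lyz2 had 4364 ± 2422 in WT and 10199.7 ± 2575 in VM. It missed the threshold (limma adjusted p = 0.144), as did Chil3 (1.48 ± 0.53, limma adjusted p = 0.367). Of 15 pan-leukocyte markers 5 rose (10 adjusted over the list alone, limma camera adjusted p = 9.2e-13, and adjusted p = 0.0508 with an estimated correlation). The number called was 9 with Xist as a covariate and 3 without VM 10 (median 2.12 and 1.28, against 1.56). Among those that rose was Ptpn6 (32.8 ± 9.56 to 183 ± 81.0, limma adjusted p = 0.00992). The others, picked in the same way, were Coro1a (1.98 ± 0.38), Cd52 (2.62 ± 0.48), Cd53 (1.66 ± 0.32) and Vav1 (2.87 ± 0.59). Ptprc, the CD45 antigen excluded by the gate, had 145 ± 38.8 normalized reads in WT and 365 ± 123 in VM (limma adjusted p = 0.0574, and 0.0192 without VM 9), and Arhgdib was at 0.46 ± 0.25. Neutrophil markers had the largest score difference of all lists, 3.07 ± 0.86 in WT and 6.99 ± 1.95 in VM (exact p = 0.0159, limma camera adjusted p = 6.1e-14, and adjusted p = 0.0677 with an estimated correlation). Of the 11, 1 passed the threshold (9 adjusted over the list alone), Mmp8, whose groups overlap (5.87 ± 1.15, limma adjusted p = 0.0337). Its call ended without WT 1, 4 or 6 or VM 3, 7, 8 or 10 (0.00533 to 0.126). The list was not called with the pan-leukocyte score as a covariate (median -0.32 against 3.57, camera adjusted p = 0.264). It was called with Xist as a covariate, with 6 members higher (median 5.40, camera adjusted p = 2.9e-15). The abundant S100a8 and S100a9 had 1157 ± 1471 and 799.9 ± 893 normalized reads in VM against 44.6 ± 27.4 and 48.6 ± 37.1 in WT (limma adjusted p = 0.0728 and 0.169). S100a8 had 3716 in VM 10 and 163 to 1077 in the other VM libraries, and passed without VM 9 or VM 10 (0.0394 to 0.197).

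Of 8 erythroid markers 2 rose (4 adjusted over the list alone, limma camera adjusted p = 1.2e-09, and adjusted p = 0.111 with an estimated correlation). Their score was 10.67 ± 1.11 in WT and 12.75 ± 0.72 in VM (exact p = 0.00794). When the pan-leukocyte score was a covariate 0 were called and the list did not pass (median -0.12 against 1.44, camera adjusted p = 0.757), whereas with Xist 4 were called and it passed (median 2.29, camera adjusted p = 1.9e-14). Those that rose included Epb4.2, a protein of the red cell membrane skeleton, at 4.87 ± 5.01 and 139 ± 67.8 normalized reads (limma adjusted p = 0.00247). Haemoglobin transcripts took 0.878% to 4.90% of reads in WT and 2.62% to 10.7% in VM. The abundant Hba-a2 and Hbb-bs did not pass (1.14 ± 0.55 and 1.25 ± 0.56, limma adjusted p = 0.532 and 0.500). T and NK cell markers did not pass (limma camera adjusted p = 0.221, Cd2 0.50 ± 0.50, Lck 1.00 ± 0.59, Klrb1c -3.27 ± 0.89), except without VM 7 (camera adjusted p 0.0304 to 0.462 with 1 mouse left out). B cell markers did not either (0.264, Ebf1 -1.43 ± 0.58, Cd79a 0.39 ± 0.63, Cd22 3.29 ± 0.91). Platelet markers did not pass (limma camera adjusted p = 0.107, and 0.0231 to 0.289 with 1 mouse left out, the lowest without WT 5), with Clec1b at 0.11 ± 0.29, Itgb3 at -0.93 ± 1.13 and Tubb1 at 0 reads in WT and 14.1 ± 17.2 normalized reads in VM. Adjusted over the list alone, 1 T and NK cell marker was lower, 1 B cell marker higher and 0 platelet markers were called. Epithelial markers (limma camera adjusted p = 0.917, Sftpc 0.02 ± 0.57, Sftpa1 -0.08 ± 0.43, Krt8 -1.64 ± 0.47) did not pass, with 0 adjusted over the list alone. They passed as higher with Xist as a covariate (median 0.93, camera adjusted p = 0.00103) and as lower with the pan-leukocyte score (median -1.55, 0.00129), with the erythroid score (0.00103) or without WT 1 and VM 10 (0.00950). Fibroblast markers did not pass either (0.917, Inmt 0.23 ± 0.38, Dcn 0.73 ± 0.43, Npnt -1.15 ± 0.31), with 1 lower adjusted over the list alone, a positive mean and a negative direction in fry. Nor did smooth muscle markers (0.699, Postn -0.42 ± 0.50, Cox4i2 -0.22 ± 0.35, Myh11 -0.54 ± 0.33, with 0 adjusted over the list alone), except as lower with the pan-leukocyte score as a covariate (median -1.30, camera adjusted p = 0.0112).

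**Figure D3:**
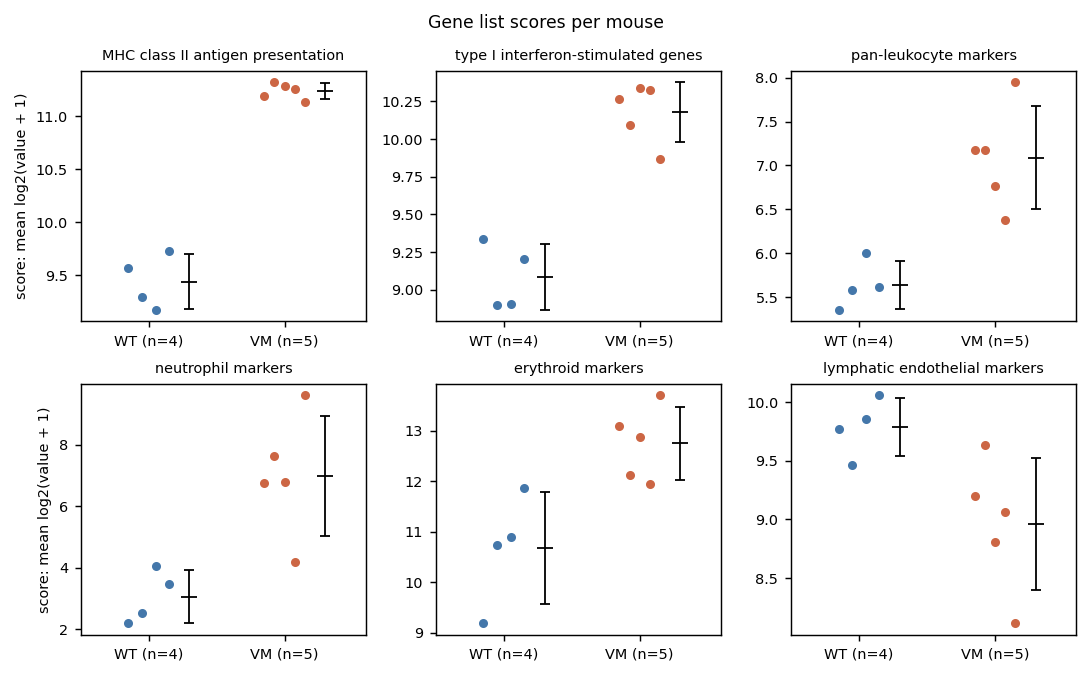
Scores (mean log2(value + 1) of the tested members; vertical axes do not start at 0) of 6 gene lists in each WT mouse (blue, n = 4) and VM mouse (red, n = 5), with mean and SD beside the points. The MHC class II score averaged 9.44 in WT and 11.2 in VM, and the neutrophil score spreads widely within VM.

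Genes induced by tissue dissociation were lower in VM for all 21 members, none past the threshold over all genes or adjusted over the list alone (median -0.78, limma camera adjusted p = 0.000252, and adjusted p = 0.508 with an estimated correlation). The list was not called with Xist as a covariate (median 0.07, camera adjusted p = 0.937) and was with the pan-leukocyte score (median -2.45, camera adjusted p = 3.4e-16). Its score overlapped between the groups (13.23 ± 0.70 and 12.30 ± 1.12, exact p = 0.206). The most abundant members were Hspa8 (-0.31 ± 0.28) and Dusp1 (-0.52 ± 0.31). The member with the smallest p was Dnajb1 (-1.16 ± 0.53, limma adjusted p = 0.516, and 0.0421 without WT 1). Of the 6 sex-linked genes none passed, and none did adjusted over the list alone (limma camera adjusted p = 0.374, and 0.0395 with the pan-leukocyte covariate, 0.00995 with the erythroid covariate and 0.00475 without WT 1 and VM 10), but they were unevenly spread. Xist had 2092 normalized reads in WT 1 and 1712 to 2562 in VM 3, 7, 8 and 9. It had at most 6.40 in the other libraries, which had the high values of Ddx3y. Read as a sign of sex, this makes WT 1 and VM 3, 7, 8 and 9 female and the others male. Sex is then unbalanced between the groups and partly confounded with genotype. With Xist as a covariate limma called 135 genes higher and 40 lower, including 93 of the 141. Without WT 1 and VM 10 it called 159 and 67, but then every WT library had the high Ddx3y values and every VM library the high Xist values. VM 10 stood apart from the other VM libraries, with 2340 genes at 0 against 1081 to 1334, 18.8% of its reads in its 10 most abundant genes and haemoglobin at 10.7%. It lay at the end of the main component of variation (32.0% of the variance; exact p between groups = 0.0238), while the next component (19.0%) had an exact p of 0.0556. With the pan-leukocyte score as a covariate 15 genes were higher and 0 lower, and with the erythroid score 12 and 0. The 46 named genes past the threshold kept a median of 114% and 96.5% of their log2 fold changes with these covariates. Their standard errors grew 1.92-fold and 1.64-fold, since both scores are themselves higher in VM.

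The authors' deposited table called 339 genes at an adjusted p under 0.05, 249 of them higher and 90 lower in VM. It includes 139 of the 141 genes called by limma, all 139 in the same direction. Across 13997 genes the fold changes of the authors' deposited table correlated with those of limma (Pearson r = 0.915, Spearman rho = 0.940), though genes are not independent replicates. In the authors' deposited table Cd74 had a log2 fold change of 2.73 and an adjusted p of 2.5e-19, Serpina3g 3.17 and 2.0e-26, and Reln -1.52 and 1.9e-05. DESeq2 on the recovered reads called 366 genes, 273 higher and 93 lower, including all 339, with log2 fold changes equal to those of the authors' deposited table within 8.7e-08.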

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

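The tests of single libraries for distance from their group, of the count of genes and lists over other splits, of VM 10 as the only source of a pattern and of Xist as a covariate for the leukocyte and lymphatic markers were set before the result was seen. The other tests in this part were chosen only after it was seen: the splits of the count with an estimated correlation, the tests of explanations for MHC class II, those of neutrophils and of purity, and that of Lyve1. Of the alternatives used in them, the Xist and pan-leukocyte covariates were fixed beforehand and the erythroid covariate was not.

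In 19 of 262 sets of values, 1 library lay far from the others of its group, with a gap to its neighbour that took an unusually large part of the range. About 13.1 such sets are expected by chance. VM 10 was that library in 9 sets, WT 1 in 5, WT 4 in 2, and WT 5, VM 3 and VM 8 in 1 each. In VM 10 this held for genes with no read (2340 against 1081 to 1334; gap 0.799 of the range), for the low log2 values of Tmem173 (8.12 against 8.47 to 8.56, gap 0.798), Oas1a (10.78 against 11.33 to 11.46, gap 0.809), Irf7 (9.73 against 10.27 to 10.48, gap 0.721) and Itgb3 (0.00 against 5.46 to 6.29, gap 0.868), and for a low cell cycle score (4.39 against 5.74 to 6.15, gap 0.764). Sex-linked values set VM 10 and WT 1 apart from their groups. Xist was low in VM 10 (2.89 against 10.74 to 11.32, gap 0.931) and high in WT 1 (11.03 against 0.00 to 1.55, gap 0.860), Ddx3y was high in VM 10 (11.74 against 0 to 1.598, gap 0.864) and low in WT 1 (0.00 against 11.55 to 11.94, gap 0.968), and the sex-linked score followed (gaps 0.858 and 0.941). WT 1 was also high in Cxcl10 (5.62 against 4.27 to 4.44, gap 0.872) and had the only Ubd reads of the WT libraries (gap 1). WT 4 was high in Ypel2 (10.05 against 9.85 to 9.88, gap 0.876) and had the only Cd22 reads of its group, and WT 5 the only Mmp8 reads (gap 1 in both). The chemokine score was low in VM 8 (5.94 against 6.39 to 6.56, gap 0.723) and the cell death score high in VM 3 (9.29 against 9.01 to 9.09, gap 0.734).

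The counts of genes were set against 100 of the splits of the 9 libraries into 4 and 5. For genes higher in VM, 1 of 100 splits, the real one, gave 122, and the highest other gave 15. This share is under the limit set beforehand and is the smallest that 100 splits can give. The real split also sets most libraries with high Xist apart from most with high Ddx3y, so it does not stand for genotype alone. For genes lower in VM, 2 of 100 splits, the real one included, gave 19 or more, which is under the limit set beforehand. The other one gave 27, more than the real split, so the genotype grouping did not stand out for this count. That split set WT 4, 5, 6 and VM 10 against the rest, follows the Xist and Ddx3y values and called 42 genes in all, which points to a structure of the samples. With Xist as a covariate 40 genes were lower in VM. For lists called with the preset correlation, 8 of 100 splits gave 18 or more and the highest gave 25 (VM 3, 7, 8 and 9 against the rest), so chance is not excluded for that count. With an estimated correlation 1 of 100 splits gave 6, the real one, and the highest other gave 1. This is again the smallest share possible, in a test chosen after the result was seen.

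MHC class II genes were higher in VM by a mean of 1.79 log2 units (camera adjusted p 4.6e-23 to 2.1e-11 over the alternatives). The summed excess of B cell, myeloid and pan-leukocyte markers was 9787 normalized reads (2736 without Lyz2 and Chil3). That was 6.12% of the Cd74 excess of 159860, and Cd79a, abundant in B cells, differed by 10.1. How many Cd74 reads such leukocytes hold per marker read was not measured. The share therefore cannot decide whether RNA of leukocytes is the source. With Xist as a covariate 8 of the 8 called class II genes were still called (2 with the pan-leukocyte score, where the median was 2.46 and the list passed). With the erythroid score the list mean was 1.83 (camera adjusted p = 2.3e-14, preset correlation), in a fit that called 12 genes in all. The erythroid fit argues against the haemoglobin share as the whole source. The Xist covariate rests within the groups on WT 1 and VM 10, and VM 10 stood apart in other ways. The class II score of WT 1 was 9.57 against 9.17 to 9.73 in the other WT libraries. That of VM 10 was 11.13 against 11.19 to 11.32 in the other VM libraries. So few libraries cannot settle the sex-linked imbalance. Endothelial expression of class II genes in VM mice stays as a hypothesis, beside leukocyte RNA. Dendritic cells rich in class II RNA that passed the gate were not tested apart and stay open. Their transcripts Itgax (30.3 ± 15.6 normalized reads in VM, 2.07 ± 0.71), Irf8 (209 ± 48.7, -0.20 ± 0.34) and Ccr7 (22.8 ± 17.2, 0.17 ± 0.86) were picked after their values were seen. Genes picked in this way cannot decide it, and the list of monocyte, macrophage and dendritic cell markers was higher (median 1.54).

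Leukocyte transcripts were higher in VM although CD45-positive cells were gated out. Of the neutrophil markers 11 of 11 were more than 1 log2 unit higher. Whole neutrophils or their RNA in the sorted VM samples stay open, since this rise prompted the explanation and does not test it. A lower endothelial purity as a whole would raise the markers of other types alike. The epithelial, fibroblast and smooth muscle scores differed by -0.02, 0.10 and -0.11 log2 units, VM minus WT (exact p = 0.968, 0.786 and 0.778). The pan-leukocyte score exceeded their mean by 1.46 log2 units more in VM (exact p = 0.00794), but its rise prompted the question. These values show no general rise of other types. Epithelial cells and fibroblasts had gates of their own, so a lower purity limited to leukocytes stays open. The pan-leukocyte list stayed higher without VM 10 (mean 1.23, camera adjusted p = 4.3e-11) and with Xist as a covariate (mean 1.90, camera adjusted p = 3.4e-12). The first value argues against VM 10 alone as the whole source. The Xist covariate depends within the groups on WT 1 and VM 10, so it cannot settle the sex-linked imbalance. Over 23 alternatives the camera adjusted p of the list was 9.7e-17 to 0.00234, leaving out the fit with its own score as a covariate. These p-values use the preset correlation, and with an estimated correlation the list missed the threshold in the main fit (adjusted p = 0.0508). Whether more leukocytes were in the VM lungs or more of them passed the gate stays open, since the samples hold no measure of the gate.

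Lymphatic endothelial markers were lower in VM, with a mean log2 fold change of -0.82. VM 10 alone is not the source, since without it the mean was -0.61 (camera adjusted p = 9.2e-06). With Xist as a covariate the mean was -1.15 (camera adjusted p = 2.0e-07, and 1.3e-07 to 0.338 over the alternatives). Within the groups that covariate depends on WT 1 and VM 10, so it cannot settle the sex-linked imbalance. With the pan-leukocyte score as a covariate, however, the call was lost (mean -0.24, camera adjusted p = 0.338), as it was with an estimated correlation (adjusted p = 0.111), so a shared source with the leukocyte difference stays open. Fewer lymphatic cells with unchanged expression would lower all members alike, but Lyve1, at -0.20 ± 0.29, lay 0.68 log2 units above the mean of the others relative to WT, with an exact p of 0.0714. Fewer cells and lower expression per cell cannot be told apart here, because Lyve1 is also made by other lung cells and its difference did not pass the test.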

How the results depend on the processing

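The alternatives of edgeR and DESeq2 on recovered reads, the erythroid covariate and the fit without WT 1 and VM 10 were tests chosen after seeing the data. In all alternatives all 141 called genes kept their sign. Of 2244 values of named genes under alternatives, 250 lost the call and 26 gained it. 88 values, of 24 genes, changed sign, all of them past the threshold with neither setting. Of 885 list means 74, of 18 lists, changed sign, 65 of them past the threshold with neither setting. Lists lost the call in 20 cases and gained it in 29 with their test direction kept. The MHC class II list passed in all 24 alternatives with the preset correlation.

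Against 122 genes higher and 19 lower in limma, the counts were 48 and 7 without trend, 273 and 93 in DESeq2, 89 and 15 in edgeR, and 42 and 3 at an adjusted p under 0.01, a stricter threshold. They were 15 and 0 with the pan-leukocyte covariate and 12 and 0 with the erythroid covariate, where standard errors grew 1.92-fold and 1.64-fold in the median. 35 genes were lower with array weights, 29 with a pseudocount of 5, 40 with the Xist covariate and 67 without WT 1 and VM 10 (159 higher). The share of higher genes, 86.5% in limma, was 85.7% with quantile normalization and 88.5% with median centring. With 1 mouse left out, 53 (without WT 4) to 144 (without WT 1) genes were higher and 7 (without WT 6) to 31 (without WT 1) lower. Without VM 3 there were 68 and 11, and the lower count was 9 without WT 4, WT 5 or VM 9 and 11 without VM 8. The count of lists, 18, was 6 with an estimated correlation. Where a list passed with or without the alternative, the test direction changed for epithelial markers with the Xist covariate (mean 0.775, and 0.951 in edgeR), for dissociation genes with the Xist covariate (mean -0.22 with a positive test direction, and 0.016 in edgeR), and with the pan-leukocyte covariate for NF-kB targets (-0.16) and neutrophil markers (-0.64). The cause was not tested. No paired analysis was possible because no number in the labels is shared between the groups. Depth limits genes near the floor of 3 reads per library, such as C4b, Ubd and Mmp8, whose fitted folds depend on the pseudocount.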

Other observations

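The score differences of MHC class II and of erythroid membrane genes, the erythroid covariate and the share of change kept for Apol11b, and the tests on cardiac muscle genes were tests chosen only after the result was seen. Some genes outside the lists fixed beforehand are named here after their values were seen and stand for no group. Slfn2, a Schlafen family gene needed for T cell and monocyte quiescence, rose (1.40 ± 0.16, limma adjusted p = 0.00114), as did Apol10b (1.16 ± 0.20, limma adjusted p = 0.0129) of the family of Apol11b and Serpina3i (3.89 ± 0.82, limma adjusted p = 0.0404) of the family of Serpina3f. So did xanthine dehydrogenase Xdh (0.91 ± 0.16, limma adjusted p = 0.0188) and argininosuccinate synthase Ass1 (0.74 ± 0.16, limma adjusted p = 0.0393). Lap3, a leucine aminopeptidase, rose too (1.06 ± 0.18, limma adjusted p = 0.0129).

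Among further genes that fell were Slco2b1, an organic anion transporter, from 504 ± 158 to 108 ± 24.9 normalized reads (-2.20 ± 0.25, limma adjusted p = 0.00114), and the potassium channel Kcnn3 (-1.41 ± 0.24, limma adjusted p = 0.0137). Cd209a, a lectin of dendritic cells and some endothelia, had 175 reads in the WT libraries and 0 in all VM libraries, at least 14.5-fold lower against the floor of 3 reads per library (limma adjusted p = 0.00630). Most other myeloid transcripts went the other way. Wfdc17 (4.66 ± 0.67, limma adjusted p = 0.00630), Tlr13 (5.23 ± 0.73, limma adjusted p = 0.00398) and the Fc receptor Fcgr4 (4.48 ± 0.76, limma adjusted p = 0.0129) rose. Mrc1, the mannose receptor of tissue macrophages and lymphatic vessels, had 795 ± 148 normalized reads in WT and 324 ± 155 in VM and did not pass (limma adjusted p = 0.0732).

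The MHC class II score differed more between the groups than that of type I interferon-stimulated genes. The difference of the scores was 0.36 ± 0.13 in WT and 1.06 ± 0.17 in VM (SD, n = 4 and 5), 0.70 log2 units more in VM (exact p = 0.00794, the smallest possible). A candidate explanation is interferon gamma acting in addition to type I interferon. The difference is the observation that prompted it and so does not test it, and it stays open. Ifng had 6 reads over all libraries, 5 of them in WT 5. T and NK cell markers remained in the samples and did not pass as a list (limma camera adjusted p = 0.221). The gate was set against CD45-positive cells, so the lymphocytes of the lung as a whole were not sampled here.

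Erythroid membrane genes differed more between the groups than globins did. The difference of their means was -11.77 ± 0.71 in WT and -9.66 ± 0.33 in VM, 2.12 log2 units more in VM (exact p = 0.00794), the smallest p possible. A different mix of red cell stages is a candidate explanation, but this difference prompted it and does not test it. The rise of Apol11b followed the erythroid score in part. With that score as a covariate its log2 fold change went from 4.55 ± 0.71 to 1.97 ± 0.27 and it was still called (limma adjusted p = 0.0241, 1.4e-07 to 0.496 over the alternatives). It kept 43.3% of its change, against a median of 96.5% for the 141 called genes, 5 of which kept less. The score averages globins with membrane genes that rose more than they did. A change that remains after this covariate therefore cannot exclude red cell RNA as the whole cause, which stays open.

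Cardiac muscle genes tended lower in VM. Of 9 such genes that did not prompt the question, 5 lay more than 1 log2 unit lower. Over all 13 tested, including the 4 that prompted it, 10 were negative and 2 were called lower, Actc1 (-3.84 ± 0.83) and Tcap (-4.16 ± 0.84). Myl4 (0.04 ± 0.33), Pln (0.87 ± 0.32) and Ckm (0.56 ± 1.03) did not follow. Less heart muscle RNA, for example from the muscle sleeves of pulmonary veins, may account for part of this, but the members that moved apart leave it undecided.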
